A study of Schizosaccharomyces pombe
Saccharomyces cerevisiae with 8 samples.

How the data were processed

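Total RNA and 4-thiouracil-labelled RNA were measured in a Sua7 degron strain of S. cerevisiae. Per the labels' protocols, S. pombe cells were mixed in before extraction at 3 parts to each part of S. cerevisiae, ribosomal RNA was depleted, and stranded libraries were made from 800 ng of total RNA or 300 ng of newly synthesized RNA. The genome build was sacCer3 and bcl2fastq 2.17.1.14 was used, per the submitters' processing notes. The aligner, the counting tool and whether counting used strand are not given in the sources used here, so overlapping and antisense genes, and paralogs of near-identical sequence, are uncertain.

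The deposited counts are raw counts per gene, per the file headers. The deposited normalized signal is the raw count divided by 1 factor per library: the ratio was constant over genes within each library. The factors were 0.669 and 0.720 (nsRNA, DMSO), 1.44 and 1.45 (nsRNA, auxin), 0.881 and 0.951 (total, DMSO) and 1.15 and 1.04 (total, auxin). How the authors set them is not given in the sources used here. They differ from median-of-ratios factors of the listed genes, and S. pombe counts were not used here, so that they measure S. pombe RNA is an assumption behind every absolute change. Further deposited columns of the normalized signal per kb of transcript, 8 in number, were not used. The deposited log2 fold changes and p-values are the authors' own comparisons, per the file headers. In the authors' deposited table, 5682 genes were lower and 35 higher in nsRNA, and 4947 lower and 91 higher in total RNA, at an adjusted p under 0.05.

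The tables list 6741 genes (nsRNA) and 6605 (total RNA), each with at least 1 count. Of 6808 genes, 2119 had a symbol and 619 more were named from the deposited descriptions; where both sources gave a name, 417 of 421 were the same. Lists are therefore incomplete: 28 of 117 ribosome biogenesis symbols and 17 of 46 amino acid symbols were matched, and none of the 7 genes deleted in the strain was matched by name. Replicates of a group had a Pearson r of log2 scaled counts between 0.981 and 0.996, and a chi-square per degree of freedom between 2.89 and 13.9, more than sampling noise.

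The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with library sizes proportional to the deposited factors, genes kept by filterByExpr (minimum count 10) and Benjamini-Hochberg adjusted p under 0.05. Relative changes used TMM. Lists were tested with camera of limma 3.58.1 on voom values with an inter-gene correlation preset at 0.01. The SE printed with a log2 change is its absolute value divided by the square root of the quasi-likelihood F statistic. It is not a fitted standard error. Library medians used a pseudocount of 0.5. The design, the alternatives, the 26 lists and the rule for named genes were fixed before the data were examined. The design assumed that a shift of all genes cancels in camera, which did not hold for the deposited scaling in nsRNA. Named genes were of 3 kinds. The 6 lowest and 6 highest log2 changes, and for the interaction the 4 largest in each direction, were taken among genes past the threshold with the same sign in all 4 library pairs and a mean scaled count of at least 100. Where fewer than 6 rose, the genes nearest to no change or above were added as values. For each list the 2 members with the highest mean were named whether or not they passed, and SUA7 and genes of the 2 mating types were named as checks. Alternatives were DESeq2 1.42.0, other scalings, other filters, a threshold of 1 on the log2 change, a replicate block, all 8 libraries in one fit and each library left out. Tests of annotation terms and of lists ranked by log2 change (cameraPR) were added after the data were seen.

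The nsRNA and total RNA libraries of one culture were taken from the labels' protocol to share an extract; their deviations from the group means correlated at 0.01 (DMSO) and 0.09 (auxin). The fits were tested on simulated data, drawn from the real means and library sizes with 200 changed genes. For nsRNA on the deposited scaling (5810 genes), 100% of genes lowered by 2 and 64.0% of those lowered by 1 (log2) were recovered; for total RNA (5495 genes) the shares were 98.0% and 38.3%. Unchanged genes made up 5.11% of the nsRNA calls and 5.00% of the total RNA calls, at a dispersion of 0.03 and with no shift of the other genes. The real counts had been fitted before this simulation was made. Classes by intron or TATA box were not analysed here.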

Results

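The series measured RNA in budding yeast, Saccharomyces cerevisiae, after removal of Sua7, the yeast form of the general transcription factor TFIIB. Sua7 carried an auxin-dependent degron tag in cells that express the plant receptor OsTIR1, so that auxin leads to degradation of the tagged protein. Cells received 500 µM auxin or the carrier DMSO for 30 min, followed by 6 min with 5 mM 4-thiouracil, a base analog built into RNA as it is made. Libraries were made from total RNA and from the purified labelled fraction, called newly synthesized RNA (nsRNA) here. There were 8 libraries in 4 groups of 2. The nsRNA libraries held 9496247 and 11779971 counts in DMSO and 1291241 and 1753672 in auxin. The total RNA libraries held 8275038 and 10543351 counts in DMSO and 7010247 and 7181104 in auxin. The labels number the replicates without saying that they were separate cultures, so p-values measure the spread between these samples, which may be technical.

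The first comparison asked how nsRNA changed after auxin, which targets Sua7 for degradation. Every library came from the Sua7 degron strain, with no strain lacking the degron given auxin. An effect of auxin itself therefore cannot be told apart from loss of Sua7, and the libraries do not measure Sua7 protein. On the deposited scaling, nsRNA fell at nearly all genes: 5659 of 5800 tested genes were lower after auxin and 76 were higher. The median gene changed by -4.08 on the log2 scale, which leaves 5.93% of the DMSO level. Of the genes that fell, 5328 fell by more than 3 on the log2 scale. The median gene of each library lay at -0.12 and 0.12 in DMSO and at -4.28 and -3.84 in auxin, relative to the DMSO mean. An exact two-sided permutation test of these library medians gave p = 0.333, the smallest that 2 against 2 libraries allow. SUA7 RNA itself (chromosome XVI, 710101 to 711138 in sacCer3) was among the transcripts that fell, with 2577 ± 156 scaled counts in DMSO and 207 ± 26.4 in auxin (SD, n = 2 each), a log2 change of -3.64 (SE 0.37, edgeR adjusted p = 6.62e-23). The degron acts on the protein, so this value does not check the treatment labels. The call counts come from edgeR's quasi-likelihood test. The number of higher genes was 32 with DESeq2 and 11 at a mean count of at least 50. With TMM scaling on S. cerevisiae genes, which sets the typical gene near 0, 1601 genes were higher and 1723 lower. The absolute direction of the whole set therefore rests on the deposited factors. A fall relative to SCR1, the RNA of the signal recognition particle, needs no factor. Raw nsRNA counts of SCR1 were 59309 and 63373 in DMSO and 81299 and 92678 in auxin, while the total counts fell. The share of mitochondrial counts went from 0.0543 and 0.0445% in DMSO to 0.595 and 0.520% in auxin.

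**Figure D1:**
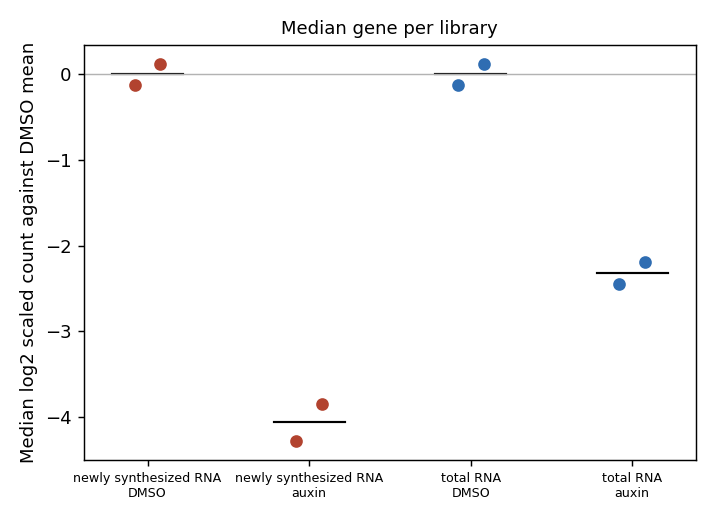
Median over tested genes of the log2 scaled count in each library, relative to the mean of the DMSO libraries of the same RNA kind. Points are libraries and bars are group means of 2 libraries. The nsRNA auxin libraries lie at -4.28 and -3.84, and the total RNA auxin libraries at -2.45 and -2.19.

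Among genes with a mean scaled count of at least 100, the largest called falls in nsRNA were at PLM2 (chromosome IV, 1451353 to 1452918), with 403 ± 46.2 scaled counts in DMSO and 4.50 ± 0.478 in auxin (SD, n = 2 each), a log2 change of -6.45 (SE 0.44, edgeR adjusted p = 3.33e-44). The others by log2 change were YLR151C (-6.30), YDR380W (-6.19), YJL107C (-6.14), GAL4 (-6.05), YLR040C (-5.98). Raw counts in auxin were few, with 6 and 7 for PLM2, 4 and 10 for YLR151C, 3 and 7 for YJL107C and 5 and 8 for GAL4. YDR380W had 21 and 28, and YLR040C 13 and 32. The size and order of these falls are therefore uncertain. GAL4 encodes the activator of the galactose genes. All 137 ribosomal protein genes were lower, with a median of -3.91, as at RPL3 (-4.13) and RPL10 (-4.10). The 28 ribosome biogenesis genes (median -3.65) included NOP56 (-3.44) and DIP2 (-3.49), and all were lower. The genes of RNA polymerase I and III subunits fell at 19 of 19, with RPA190 at -2.97 and RPA135 at -3.41. Those of RNA polymerase II and general factors fell at 26 of 26, with RPB2 at -3.31 and RPO21 at -3.50. Mediator subunit genes fell at 17 of 17 (NUT1 -3.39, RGR1 -3.45), decay factors at 23 of 23 (CDC39 -4.17, XRN1 -3.90) and proteasome genes at 20 of 20 (RPN2 -3.95, RPN1 -3.95). Glycolysis and fermentation genes had a median of -4.47, with TDH3 at -3.94 and ENO2 at -4.32. Heat shock genes of Hsf1 (HSP82 -4.23, SSA1 -4.12) fell at 15 of 15, and stress genes of Msn2 and Msn4 (TPS2 -5.00, TSL1 -4.93) at 23 of 23, with a median of -4.82. Histone genes (HHT1 -4.87, HTA1 -4.74) fell at 5 of 5 and G1/S genes (RNR1 -5.10, POL2 -4.17) at 23 of 23. With TMM scaling, which moves the median of all tested genes by 3.99 in nsRNA, the changes of NOP56, DIP2, RPA190, RPA135, RPB2, RPO21, NUT1, RGR1, XRN1, RPN2, RPN1, TDH3 turned positive, and so did that of SUA7.

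Genes of nuclear oxidative phosphorylation fell at 17 of 17 (COR1 -4.22, ATP4 -4.12), amino acid synthesis at 17 of 17 (ILV2 -4.13, SER33 -4.91), sulfur and methionine metabolism at 10 of 10 (MET5 -4.48, SAM1 -4.62) and ergosterol synthesis at 15 of 15 (ERG13 -4.49, ERG11 -4.23). Drug and weak acid transporters fell at 10 of 10 (PDR5 -4.55, ATR1 -4.74), and hexose transporters at 8 of 9 (HXT3 -3.81, HXT1 -3.55). The pheromone gene MF(ALPHA)1 (-4.69) and the receptor gene STE3 (-5.06), expressed in cells of this mating type, fell with the rest. BAR1, a gene of the other mating type, had 18 and 29 counts in DMSO and 21 and 19 in auxin, and a log2 change of -1.28 (edgeR adjusted p = 0.00196). For each list of messenger RNAs from the nucleus the count of lower genes was the same when adjusted over the list alone. With TMM the changes of HXT3, HXT1 and BAR1 turned positive, and the call of BAR1 was lost with DESeq2.

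Transcripts of other RNA polymerases had higher values. Of 80 tested tRNA genes, 52 were higher in nsRNA and 4 lower, with a median of 1.47 (49 higher when adjusted over the list alone). The tRNA gene tG(GCC)P1 had 38.7 ± 6.13 scaled counts in DMSO and 161 ± 26.8 in auxin (SD, n = 2 each), a log2 change of 2.05 (SE 0.35, edgeR adjusted p = 4.38e-09), and tW(CCA)P changed by 1.66. These tRNA counts were low, 23 and 31 in DMSO for tG(GCC)P1, and tRNA genes of near-identical sequence can share reads. Of the other genes above the mean count of 100, the snoRNA snR52 (0.83) and YLR343W (1.15) rose, while Q0255 (0.24) and YBR099C (0.18) did not pass the test. SCR1, the RNA of the signal recognition particle, had a log2 change of -0.55 and RPR1, the RNA of RNase P, of 0.09, neither past the threshold. SCR1 took 0.625 and 0.538% of nsRNA counts in DMSO and 6.30 and 5.28% in auxin. Of 11 mitochondrially encoded genes, 2 were lower (1 adjusted over the list alone) and the median was -0.20 (COX2 -0.45, COX3 -0.54). The list of snoRNAs leaves out snR52, a transcript of RNA polymerase III, and, by its name pattern, any snR70 to snR79. It fell at 57 of 57 (snR86 -3.73, snR30 -3.82) and the spliceosomal RNAs of RNA polymerase II at 3 of 3 (LSR1 -4.38, SNR19 -4.33). The calls of BAR1 and snR52 were lost without at least 1 library. With TMM scaling the values of SCR1, COX2, COX3, snR86 and snR30 turned positive.

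Whether a list fell more or less than other genes was tested with limma camera. The tRNAs (camera adjusted p = 1.23e-229, adjusted p = 0.104 with an estimated correlation) and the mitochondrially encoded genes (camera adjusted p = 9.30e-25, adjusted p = 0.236 with an estimated correlation) lay above other genes. Glycolysis and fermentation (camera adjusted p = 7.06e-04, adjusted p = 0.989 with an estimated correlation), Hsf1 heat shock (camera adjusted p = 0.0392, adjusted p = 0.989 with an estimated correlation) and G1/S genes (camera adjusted p = 0.0392, adjusted p = 0.989 with an estimated correlation) lay below. Of 23 lists, 6 passed with the preset correlation and 0 with estimated correlations. Without auxin replicate 1 the number was 10, without auxin replicate 2 11, and without DMSO replicate 1 or 2 it was 4. The calls of the tRNAs and the mitochondrially encoded genes held in each of these fits. Without DMSO replicate 1 or 2 the calls were lost for glycolysis (adjusted p = 0.194 and 0.139), Hsf1 genes (0.782 and 0.699) and ribosomal proteins (0.516 and 0.564), and without auxin replicate 1 or 2 for G1/S genes (0.128 and 0.124). With TMM at the preset correlation, camera placed 6 lists below other genes and 5 above. Hsf1 genes did not pass (adjusted p = 0.0705), while glycolysis and fermentation (1.85e-04) and G1/S genes (9.62e-05) did. Histones (0.00582), nuclear oxidative phosphorylation (0.0255) and ergosterol synthesis (0.0255) also lay below with TMM, without a call in the main test. When ranked by log2 change, no list below other genes passed but Msn2 and Msn4 stress. That list did not pass the main test (camera adjusted p = 0.432, adjusted p = 0.989 with an estimated correlation), and passed with TMM (adjusted p = 9.62e-05) and by rank (adjusted p = 5.03e-05), both at the preset correlation. The main camera test ranks genes by a moderated statistic, and with nearly every gene far below 0 that statistic followed the mean level across genes (Spearman rho -0.55, against -0.01 with TMM). Camera placed the ribosomal proteins lower than other genes (adjusted p = 0.0392, adjusted p = 0.989 with an estimated correlation), although their median lay 0.164 above that of all genes, and with TMM the direction turned (adjusted p = 0.235). The median and the test also differed in direction, without a call, for ribosome biogenesis, RNA polymerase I and III subunits, RNA polymerase II and general factors, mRNA decay factors, proteasome, amino acid biosynthesis, sulfur and methionine and snoRNAs. Relative to the typical gene, edgeR with TMM called 1601 genes higher and 1723 lower of 5833. In nsRNA this balance turned with other relative scalings, to 1737 higher and 1563 lower with median-of-ratios factors, and to 1383 and 922 in DESeq2 with its own factors.

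The second comparison asked how total RNA changed over the same time. Total RNA fell at 4946 of 5479 tested genes and rose at 79, with a median log2 change of -2.34, which leaves 19.8% of the DMSO level. The middle part of the genes, from the lower to the upper quartile, kept between 12.7 and 36.0%. The library medians were -0.13 and 0.13 in DMSO and -2.45 and -2.19 in auxin, and the exact permutation test again gave its smallest p, 0.333. The summed scaled count changed far less than the median gene, by -0.66. The number of higher genes was 20 at a mean count of at least 50 and 146 with all 8 libraries in one fit. SUA7 RNA fell by 2.68 on the log2 scale. With TMM, 1833 genes were higher and 2305 lower.

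Among genes with a mean scaled count of at least 100, the largest called falls were at YBR047W (chromosome II, 331833 to 332360), with 268 ± 38.9 scaled counts in DMSO and 6.73 ± 2.75 in auxin (SD, n = 2 each), a log2 change of -5.27 (SE 0.36, edgeR adjusted p = 7.33e-46), followed by YKL071W (-4.89), FRM2 (-4.86), AIM17 (-4.85), YIL098C (-4.73), RHB1 (-4.67). Raw counts in auxin were few for several of these, with 10 and 5 for YBR047W and 9 and 7 for YIL098C, against 49 and 64 for YKL071W. By the same limit on the mean scaled count, the highest called changes were at tW(CCA)P (3.76), YOR242C (2.48), YLR343W (1.64), CIS1 (1.03), YOR297C (0.67) and YNL008C (0.66). Of the ribosomal protein genes, 37 of 137 were lower (27 adjusted over the list alone), with a median of -0.16, and RPL10 (-0.35) and RPS31 (-0.09) did not pass. Across all genes, which are not independent replicates, the log2 change in total RNA followed the mean level (Spearman rho 0.445, and 0.374 with TMM), and camera does not match lists on level. The ribosomal protein list fell less than other genes (camera adjusted p = 1.34e-33, adjusted p = 0.903 with an estimated correlation). The same held for glycolysis and fermentation (7 of 10 lower, median -0.49; camera adjusted p = 0.00566, adjusted p = 0.903 with an estimated correlation), with FBA1 at -0.28 and ADH1 at -0.45, and for amino acid synthesis (14 of 17 lower, median -0.80; camera adjusted p = 0.0276, adjusted p = 0.903 with an estimated correlation), with ILV2 at -0.72 and GDH1 at 0.11, a call lost without auxin replicate 2 (adjusted p = 0.0571). The listed snoRNAs, without snR52 and any snR70 to snR79, fell at 48 of 58 (47 adjusted over the list alone) with a median of -0.88 (camera adjusted p = 1.67e-08, adjusted p = 0.903 with an estimated correlation), and snR30 (-0.09) and snR86 (-0.14) did not pass. Of the spliceosomal RNAs, 1 of 3 were lower, LSR1 had -0.19 and SNR19 -0.22. Mitochondrially encoded genes had a median of 0.26, with 2 of 24 higher and 0 adjusted over the list alone (camera adjusted p = 1.63e-22, adjusted p = 0.903 with an estimated correlation). Q0050 had 0.19 and Q0055 0.20. Q0050 (13818 to 16322) lies within Q0055 (13818 to 18830), so these list members can share reads. Of 62 tRNA genes, 47 were higher (median 2.65; camera adjusted p = 3.79e-88, adjusted p = 0.291 with an estimated correlation), and the mitochondrial tRNA tP(UGG)Q changed by 0.64. Only 45 of the 62 were nuclear (median 3.25), against 78 of the 80 tested in nsRNA (median 1.55). The tRNA list medians of the 2 RNA kinds therefore cover unlike sets. SCR1 (-0.21) and RPR1 (0.31) did not pass.

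Histone genes fell at 5 of 5 with a median of -3.10 (HTA2 -3.10, HHT1 -2.90). Msn2 and Msn4 stress genes fell at 18 of 18 (GLK1 -2.43, TPS2 -3.09), more than other genes (camera adjusted p = 0.0276, adjusted p = 0.903 with an estimated correlation), a call lost without auxin replicate 2 (adjusted p = 0.117) and when ranked by log2 change (adjusted p = 0.155). Mediator genes fell at 17 of 17 (NUT1 -1.60, RGR1 -1.81), G1/S genes at 20 of 20 (POL2 -1.03, RFA2 -2.41), decay factors at 22 of 22 (XRN1 -0.60, CDC39 -1.49) and proteasome genes at 20 of 20 (RPN2 -0.87, RPN1 -0.64). Ribosome biogenesis genes fell at 27 of 28 (NOP56 -0.89, NOP7 -0.88). The polymerase I and III subunit genes fell at 16 of 19, although RPA190 (0.29) and RPA135 (-0.43) did not pass, and those of polymerase II and general factors at 24 of 26, although RPB2 (-0.26) and RPO21 (-0.28) did not. Hsf1 heat shock genes fell at 15 of 15, with HSP82 at -2.97 and HSC82, a paralog of near-identical sequence that can share reads, at -0.70. Oxidative phosphorylation genes fell at 17 of 17 (ATP4 -1.20, COR1 -1.15), sulfur and methionine genes at 9 of 9 (SAM1 -1.38, MET5 -1.50) and ergosterol genes at 13 of 15 (ERG13 -0.55, ERG10 -0.60). Drug and weak acid transporters fell at 9 of 9 (PDR5 -1.82, YOR1 -3.13) and hexose transporters at 7 of 8 (HXT3 -1.18, HXT1 -2.78). MF(ALPHA)1 (-2.12) and STE3 (-3.81) fell, and BAR1 stood at 0.02. Of 23 lists, 7 passed camera and 0 with estimated correlations. Relative to the typical gene, 1833 were higher and 2305 lower of 5489. In total RNA this balance turned with other relative scalings, to 2038 higher and 1974 lower with median-of-ratios factors, and to 1829 and 1372 in DESeq2 with its own factors. Leaving out at least 1 library ended the calls of ADH1, ERG10, ERG13, HSC82, ILV2, NOP56, NOP7, RPN1, RPN2, XRN1, YNL008C, YOR297C and tP(UGG)Q. The median and the camera test differed in direction, without a call, for mRNA decay factors, proteasome, nuclear oxidative phosphorylation, sulfur and methionine, Hsf1 heat shock, drug and weak acid transport and alpha-cell genes. Except where given above, counts adjusted over the list alone were the same. With TMM scaling, which moves the median by 2.12 in total RNA, the values of RPL10, RPS31, NOP56, NOP7, RPA135, RPB2, RPO21, NUT1, RGR1, XRN1, CDC39, RPN2, RPN1, FBA1, ADH1, ATP4, COR1, ILV2, SAM1, MET5, ERG13, ERG10, HSC82, PDR5, POL2, HXT3, SCR1, snR30, snR86, LSR1, SNR19, MF(ALPHA)1 turned positive.

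**Figure D2:**
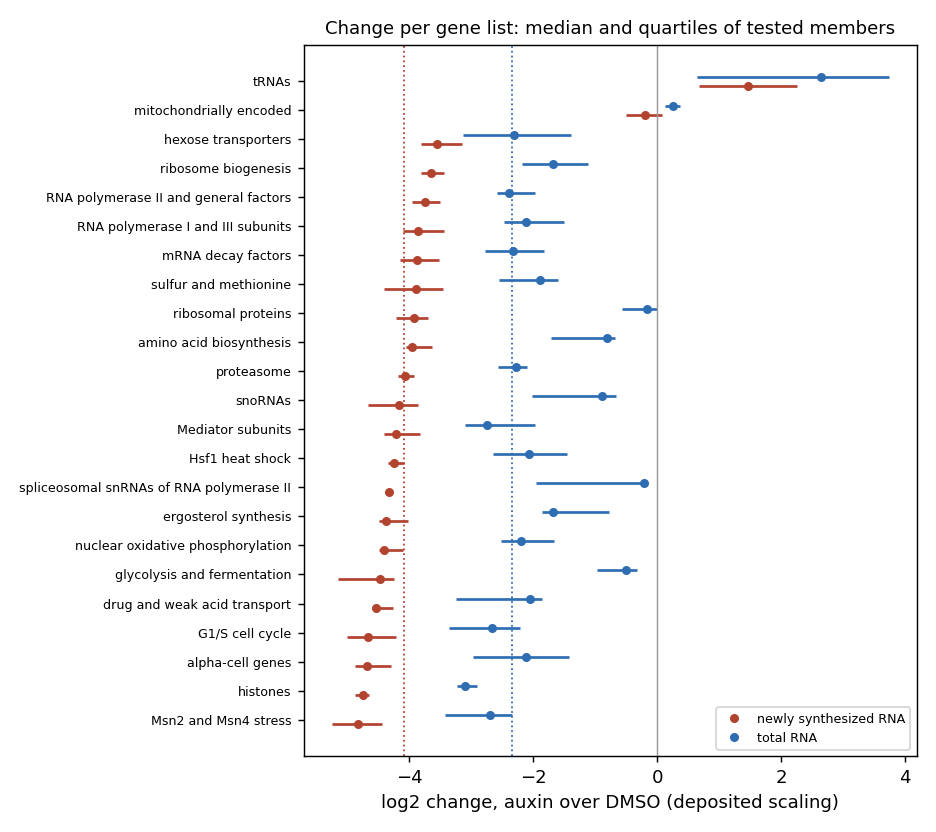
Log2 change after auxin on the deposited scaling for each fixed gene list with at least 3 tested members; points are medians and lines the quartiles over tested members, and dotted lines mark the median of all tested genes. With TMM scaling the median of all genes moves by 3.99 and 2.12; the ribosomal proteins lie at -3.91 in nsRNA and -0.16 in total RNA.

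The third comparison asked at which genes nsRNA and total RNA changed by different amounts. The interaction of RNA kind and treatment in edgeR, over all 8 libraries, called a lower change in nsRNA than in total RNA at 4600 of 5930 genes and a higher one at 2, with a median difference of -1.65 (log2). With the shared extract as a block the counts were 4986 and 2. The count of 2 became 0 without nsRNA auxin replicate 2, 1 with DESeq2, and between 0 and 3 with any 1 library left out. At a mean scaled count of at least 100 over the 8 libraries, the largest called differences were at OLE1, the fatty acid desaturase gene (-4.60 in nsRNA and 0.28 in total RNA), ENO1 (-5.68 and -0.97), YNL190W (-4.86 and -0.26) and the ribosomal protein gene RPL21B (-4.31 and 0.25). ENO1 and RPL21B each have a near-identical paralog that can share reads. With TMM scaling the interaction was split between 1679 higher and 1370 lower. Across 5433 genes tested in both, the changes of nsRNA and total RNA had a Pearson r of 0.63 and a Spearman rho of 0.49; genes are not independent replicates.

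The last comparison set the total RNA change against turnover, taken as the log2 ratio of nsRNA to total RNA in DMSO replicate 1, with the change taken from replicate 2. Across 5433 genes the Spearman rho was -0.33 and the Pearson r -0.37, described without a p since genes are not independent replicates. The difference lay in the quintile of genes with the lowest ratio, whose total RNA had a median change of -1.21. The other quintiles, in order of ratio, had medians of -2.35, -2.53, -2.54 and -2.57. The ratio divides by the total RNA level, and the total RNA change also followed the mean level (Spearman rho 0.445). Level and turnover were not separated, so the difference cannot be assigned to turnover.

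**Figure D3:**
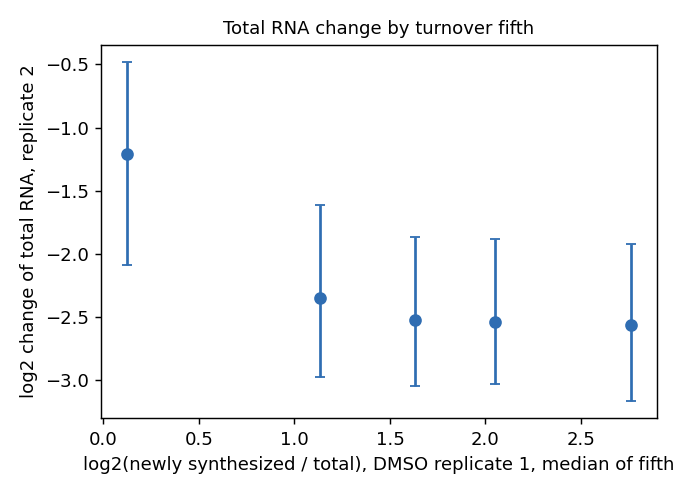
Median log2 change of total RNA (replicate 2) in quintiles of genes ordered by the log2 ratio of nsRNA to total RNA in DMSO replicate 1; bars span the quartiles over genes. The quintile of the lowest ratio lies at -1.21 and that of the highest at -2.57.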

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

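The auxin change differed between nsRNA and total RNA by the edgeR interaction test at 4600 genes, where the nsRNA change lay below that of total RNA, and at 2, where it lay above. The latter were ATP8, with a difference of 3.43 (adjusted p = 0.00317), and YGL024W, with 3.86 (adjusted p = 0.0305); YGL024W was named after its values were seen. Both rest on few counts. ATP8 had 0 and 1 nsRNA counts in DMSO and 5 and 22 in auxin, and YGL024W had 0 total RNA counts in each auxin library. With 1 library left out the difference at ATP8 went from 1.99 to 7.34, and its call was lost without nsRNA auxin replicate 2. The count of 2 became 0 without nsRNA auxin replicate 2, 1 with DESeq2, and between 0 and 3 with any 1 library left out.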

How the results depend on the processing

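TMM on S. pombe genes was not run, since S. pombe counts were not used here, and the authors' own scaling is the main one. The labels do not say whether replicate numbers pair DMSO with auxin samples. Same-numbered deviations correlated at -0.03 (nsRNA) and 0.02 (total RNA). These values cannot decide it, since libraries taken to share an extract correlated at only 0.01 (DMSO) and 0.09 (auxin). With the replicate block, 5737 genes changed in nsRNA and 5299 in total RNA (123 higher), 3240 and 4147 relative to the typical gene, with medians of -4.08 and -2.34, and 6 and 11 lists passed; with the culture block 4988 genes differed between the RNA kinds. Of the lists that passed in total RNA with the replicate block, 4 lay above other genes and 7 below, against 6 and 1 in the main test. In nsRNA 3 lay above and 3 below, against 2 and 4. The block turned the direction of Msn2 and Msn4 stress (nsRNA, adjusted p = 0.528), ergosterol synthesis (total RNA, adjusted p = 0.314), glycolysis and fermentation (total RNA, adjusted p = 0.241), ribosome biogenesis (total RNA, adjusted p = 0.101). Calls of the main test that did not pass with the block were, in nsRNA, G1/S genes (adjusted p = 0.150), Hsf1 heat shock (0.818) and glycolysis and fermentation (0.150), and in total RNA amino acid biosynthesis (0.486) and glycolysis and fermentation. With an arm of 1 library left, that library is assumed to vary like the others.

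The total counts of changed genes, higher and lower together, stayed within 1.5 times under the alternatives run, with the exceptions below. The counts in a single direction moved more. Higher genes in nsRNA numbered 76 in the main test, 123 with no filter and 11 at a mean count of at least 50, and 32 with DESeq2. Higher genes in total RNA numbered 79 in the main test, 169 with no filter and 20 at a mean count of at least 50, and 146 with all 8 libraries in one fit. DESeq2 with its own factors called 922 genes lower relative to the typical gene in nsRNA and 1372 in total RNA. With TMM, 3324 genes changed in nsRNA and 3049 differed between the RNA kinds, and 2836 differed by more than 1 on the log2 scale. The summed count in place of the median gene gave -0.66 for total RNA. Estimated correlations left 0 lists in both RNA kinds. fry, run on TMM-scaled values, tests whether a list moves one way and not whether it differs from other genes, and gave 18 lists in nsRNA and 19 in total RNA, camera on TMM-scaled values with the preset correlation gave 11 in nsRNA, and ranking by log2 change, chosen after the data were seen, gave 3. Leaving out 1 library gave 4 to 11 lists in nsRNA, the most without an auxin library. The turnover rho was -0.331 with replicates exchanged, -0.331 with all libraries and -0.349 above a mean count of 50. The causes were not tested, except that TMM sets the typical gene near 0, a shift of 3.99 in nsRNA and 2.12 in total RNA.

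By that shift, TMM reversed the log2 change of 21 named genes in nsRNA (NOP56 0.55, DIP2 0.51, RPA190 1.01, RPA135 0.57, RPB2 0.68, RPO21 0.50, NUT1 0.59, RGR1 0.54, XRN1 0.0753, RPN2 0.0351, RPN1 0.0333, TDH3 0.0440, HXT3 0.17, HXT1 0.44, COX2 3.57, COX3 3.48, SCR1 3.44, snR86 0.26, snR30 0.15, BAR1 2.71, SUA7 0.36) and in total RNA of RPL10 1.78, RPS31 2.03, NOP56 1.23, NOP7 1.24, RPA135 1.69, RPB2 1.86, RPO21 1.84, NUT1 0.52, RGR1 0.31, XRN1 1.52, CDC39 0.63, RPN2 1.25, RPN1 1.48, FBA1 1.84, ADH1 1.68, ATP4 0.93, COR1 0.98, ILV2 1.40, SAM1 0.74, MET5 0.61, ERG13 1.57, ERG10 1.52, HSC82 1.43, PDR5 0.30, POL2 1.09, HXT3 0.94, SCR1 1.93, snR30 2.03, snR86 1.98, LSR1 1.94, SNR19 1.91, MF(ALPHA)1 0.00590. With the preset correlation it turned the list direction of RNA polymerase I and III subunits (adjusted p = 0.0579), RNA polymerase II and general factors (adjusted p = 0.0119), amino acid biosynthesis (adjusted p = 0.277), mRNA decay factors (adjusted p = 0.151), ribosomal proteins (adjusted p = 0.235), ribosome biogenesis (adjusted p = 2.06e-05), snoRNAs (adjusted p = 0.187) in nsRNA, and of hexose transporters (adjusted p = 0.945), nuclear oxidative phosphorylation (adjusted p = 0.912), sulfur and methionine (adjusted p = 0.712) in total RNA. Leaving out 1 library reversed at least 1 value of Q0255 (nsRNA, -0.29 to 0.62), YBR099C (nsRNA, -0.0256 to 0.36), BAR1 (total RNA, -0.14 to 0.20), GDH1 (total RNA, -0.0134 to 0.25), Q0050 (total RNA, -0.0184 to 0.39), Q0055 (total RNA, -9.96e-04 to 0.41), snR86 (total RNA, -0.32 to 0.0513), as log2 changes, and the list direction of RNA polymerase II and general factors (nsRNA, adjusted p 0.359 to 0.979), ribosome biogenesis (nsRNA, adjusted p 0.329 to 0.662), snoRNAs (nsRNA, adjusted p 0.0102 to 0.892), sulfur and methionine (nsRNA, adjusted p 0.204 to 0.965). Of 126 named values, DESeq2 kept direction and side of the threshold for 120, ended 3 calls and added 3. With 1 library left out, 40 of 524 gene values and 10 of 184 list values lost their call. TMM ended 9 gene calls and 1 list call without a change of direction, and estimated correlations ended 13 list calls.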

Other observations

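The tests of annotation terms, of some of these terms against matched lists and of the scaling explanation for tRNAs, the Fisher tests, and the exchange of replicates in the test of unlabelled RNA were chosen after the results were seen. The terms set against matched lists were picked because they stood out, and the comparison with matched lists takes no account of that choice. In total RNA the 97 genes of mitochondrial translation, encoded in the nucleus, had a median of -3.17, and 95 were lower. The 151 genes of cytoplasmic translation had a median of -0.24, and 52 were lower. Of 10000 random lists matched on mean level, the central 95% had medians from -2.70 to -2.32 for the first and from -0.95 to -0.60 for the second. In nsRNA the mitochondrial translation genes had a median of -4.14, within the matched range of -4.26 to -4.01, and those of cytoplasmic translation -3.89, above their range of -4.12 to -3.93. Of 625 terms, 26 fell less and 7 fell more by camera, and 0 passed with estimated correlations.

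Genes of ascospore wall assembly, which act in spore formation, fell less than other genes in nsRNA (camera adjusted p = 1.04e-06, adjusted p = 1.00 with an estimated correlation). Of 37 genes, 5 rose and 32 fell. Their median was -3.64 in nsRNA and -1.71 in total RNA, for a term picked among 631 because it stood out. The central 95% of lists matched on mean level had medians from -4.29 to -3.70 in nsRNA and from -2.77 to -1.87 in total RNA, so both medians lay a little above these ranges. The camera statistic followed the mean level in nsRNA (Spearman rho -0.55), and the median scaled count of the term, 134, was lower than that of all coding genes, given below. In total RNA 32 of its genes were tested, of which 4 rose, 24 fell and 4 did not pass. Members that rose there were DIT2 (2.07), YDR523C (2.75), YLR343W (1.64) and YOR242C (2.48). Counts in DMSO were 3 and 7 for DIT2, 4 and 10 for YDR523C, 63 and 76 for YLR343W and 34 and 40 for YOR242C. DIT2 and YDR523C were named after their values were seen.

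Among nuclear coding genes, 22 rose in nsRNA and 29 in total RNA. A candidate explanation was reads from a neighbouring RNA polymerase III gene, which would place most of them within 500 bp of one. In nsRNA 1 (4.55%) and in total RNA 2 (6.90%) lay that near, against 3.91% and 3.90% of other tested coding genes (Fisher's exact test, p = 0.585 and 0.315), which argues against it for the set. The near genes were YER097W, which rose in both RNA kinds (2.20 and 3.18), and CIS1, named above for total RNA, each at 135 bp. For them this explanation stays open. YLR343W lay at 848 bp, and reads from beyond the 500 bp limit were not tested. YER097W was named after its values were seen. The median scaled count of those that rose was 19.7 in nsRNA against 624 for all coding genes, and 30.3 in total RNA against 250, although YNL008C (603) and YGL009C (8176, named after its values were seen) lay above the latter. A change of synthesis at them, and reads from S. pombe, stay open and were not tested.

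The rise of tRNA reads may reflect the scaling or the count filter. A scaling that puts all auxin values too high would raise mitochondrially encoded genes as much. The median of the tested nuclear tRNA genes (78 with a median of 1.55 in nsRNA and 45 with a median of 3.25 in total RNA, without mitochondrial tRNAs) exceeded theirs by 1.75 in nsRNA and 2.99 in total RNA (log2). A factor common to all genes does not make this relative rise. It cannot decide whether tRNA reads rose in absolute terms, since the change of mitochondrial RNA is known only on the same scaling. Summed over every nuclear tRNA gene with no filter, the scaled count rose in all 8 library pairs, which argues against the filter. The rise was 0.93 to 1.53 (log2) in nsRNA and larger, 2.36 to 3.19, in total RNA. The sums were small, 252 to 955 counts in DMSO. A change in the recovery of short RNAs and a change in tRNA synthesis were not tested.

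The nsRNA that remained after auxin may in part be unlabelled RNA carried through the purification, in which case genes with more total RNA per nsRNA would keep more signal. Across 5311 nuclear coding genes, which are not independent replicates, the nsRNA change followed the log2 ratio of total RNA in auxin to nsRNA in DMSO with a Spearman rho of 0.329, over the bound of 0.3 set before this value was seen. The margin was small: with the DMSO replicates exchanged between the measures rho was 0.276, under that bound, so the result depends on which replicate enters each measure. Both measures also divide by the nsRNA level in DMSO, and the changes of nsRNA and total RNA were themselves correlated (Spearman rho 0.49). A rho over the bound therefore cannot tell carried-over RNA from synthesis that remained. The median nsRNA change went only from -4.50 in the quintile of the lowest ratio to -4.02 in that of the highest, while the ratio went from -5.58 to -1.17. Unlabelled RNA as a partial source therefore stays open, as do synthesis without Sua7 and Sua7 left in the cells, which were not tested.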
